A study of Mus musculus with 6 samples.

How the data were processed

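Gene expression was measured by mRNA sequencing in 6 libraries of mouse embryonic fibroblasts, with 2 each of the WT line, the AIF3 clone C3 and AIF3-AIF, the same clone with exogenous AIF. Per the labels' protocols, the fibroblasts came from embryos with a floxed allele and were turned into AIF3-expressing cells with a CRE lentivirus and cloned from single cells. RNA was extracted with DNase treatment and made into libraries from mRNA. Samples were grouped by the labels.

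The table deposited by the authors holds TPM, a measure scaled for gene length and library total, in 1 column per library over 17592 genes, although its name speaks of raw data. Each column summed to 1000000, the values were not whole, and the smallest steps differed between genes. Per the submitters' processing notes, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts and edgeR were used, with no role or order. The notes name the human build hg19, while the symbols and positions in the table are of mouse, and 16590 of 16658 symbols found in GENCODE M21 (GRCm38) overlapped that gene on the same strand, or 99.6%. The gene length behind the TPM values and the strand setting of the counting are not given in the sources used here. No mitochondrially encoded gene was listed, and 27 gene names had been turned into numbers, as a spreadsheet does with names that look like dates. TPM keeps no depth, but ratios between libraries gave back whole reads, up to a common factor per gene, for 16288 genes, with a tolerance of 1e-06 reads. These were all genes above 0 in at least 2 libraries except Rn45s; 1303 further genes were above 0 in 1 library only. The log of the value of 1 read fell with log exon length, with r = -0.88 across 15391 genes. Recovered reads ran from 19.6 to 28.7 per library in units of 1000000, and Rn45s took 1.30% to 2.12% of TPM. The spread between the 2 libraries of a group holds counting noise as well as differences between libraries.

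A count model with edgeR and TMM scaling had been planned and was not used, since the values are TPM; DESeq2 was not run for the same reason. limma 3.58.1 in R 4.3.3 was fitted instead to log2(TPM + 1) with a mean per group, an intensity trend and empirical Bayes moderation, over 13003 genes with at least 0.5 TPM in at least 2 libraries. All 6 libraries shared the estimate of spread, with 3 residual and 6.56 total degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The comparisons were AIF3 vs WT, AIF3-AIF vs AIF3 and AIF3-AIF vs WT, and genes called in opposite directions in the first and second were counted as moved back. For that overlap, 100 simulations of unchanged groups shared the AIF3 libraries. Read recovery used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

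The grouping, the comparisons, 38 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, which left none of the calls in any comparison. The estimated version rests on 3 residual degrees of freedom, so it could call few lists whatever their correlation and decides neither way. In AIF3 vs WT, DNA replication genes had an estimated correlation of -0.0105, below the preset. Their camera adjusted p still went from 3.54e-04 to 0.376. Lists with at least 5 tested members entered, 30 in all, and the others were only counted. The text names Aifm1; the 6 genes with the largest change in each direction per comparison among called genes with a mean of at least 10 TPM in the higher group and no overlap between libraries; up to 4 called members of a list with the smallest p; 8 moved-back genes in each direction; and 4 genes per direction called in AIF3-AIF vs WT alone. Predicted genes without a symbol were left out, and the planned minimum in CPM was taken as TPM. Members used as checks on the cultures are named with their values. Some genes that meet these rules are not reported here.

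The alternatives were RLE and upper-quartile scaling, filters of 0 and 1 TPM, a block for the replicate number, only the groups compared, a minimum absolute log2 fold change of 1, and each library left out in turn. The planned scaling by library size alone equals TPM as deposited. Added after seeing the data were pseudocounts of 0.1 and 5 TPM, voom on recovered reads, quantile normalization, removal of trends on exon length or GC content, removal of chromosome medians, leaving out small RNA genes, and a split of the AIF3 libraries between both comparisons. Chromosome medians used genes with a mean of at least 5 TPM. On simulated data made for AIF3 vs WT over 13003 genes, limma called 44% of 50 genes changed by 0.25 on the log2 scale with the right sign, 96% at 0.5 and 100% at 1 and 2, and 9 of 12763 unchanged genes. Camera called the shifted list and 0 of the other lists. The simulated noise was drawn for each gene independently, so those lists held no correlation between genes. In the data, estimated correlations were 0.70 in cytosolic ribosome genes and 0.35 in matrix genes. False calls of camera under such correlation were therefore not tested. Read recovery on 15902 simulated genes was exact for 98.1% and exact up to a common divisor for 100%.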

Results

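Expression was measured by mRNA sequencing in mouse embryonic fibroblasts, adherent connective-tissue cells grown from embryos. The fibroblasts carried a conditional allele that, after exposure to CRE recombinase, makes the AIF3 splice form of the apoptosis-inducing factor gene in place of AIF. AIF is a flavoprotein of the mitochondrial intermembrane space, encoded by Aifm1 and needed for the upkeep of the respiratory chain. The 3 groups held 2 libraries each: the WT line, the AIF3 clone C3, and AIF3-AIF, in which exogenous AIF was put into clone C3. Recovered reads per library, in units of 1000000 reads, came to 27.9 and 19.6 in WT, 28.4 and 25.8 in AIF3, and 28.7 and 23.8 in AIF3-AIF. Replicates of a group differed by more than sampling noise, with a mean chi-square per degree of freedom of 2.75 in WT, 1.55 in AIF3 and 2.96 in AIF3-AIF. The median over genes, as a ratio to that of sampling noise alone, was lower, at 1.69, 1.12 and 1.81. Libraries of different groups differed far more, with a mean chi-square per degree of freedom from 33.2 to 98.0. WT stood apart from both other groups on the first principal component, which held 68.9% of the variance. AIF3-AIF and AIF3 were separated on the second, which held 18.7%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each genotype is a single line, so effects of the genotype and of the clone cannot be separated in any comparison.

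Aifm1 lies on chromosome X from 48474943 to 48513563 on the minus strand in the table's coordinates, which match the GRCm38 build. Its level was 88.5 and 86.8 TPM in the WT libraries, 97.7 and 96.9 in AIF3, and 204 and 196 in AIF3-AIF. Aifm1 was thus 1.03 ± 0.03 (SE) higher in AIF3-AIF than in AIF3 on the log2 scale, adjusted p = 1.29e-05. The rise of 0.15 from WT to AIF3 had adjusted p = 0.00668, and turned to -0.02 once the median of each chromosome was removed. Values per gene do not separate splice forms, so they check the added AIF but not the splicing.

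The comparison of AIF3 with WT asks how expression differs when the AIF3 form replaces AIF. With a preset correlation, camera placed the matrix, contractile and imprinted gene lists lower than other genes and the glycolysis list higher. With an estimated correlation each of them had an adjusted p = 0.376, but that version rests on 3 residual degrees of freedom and could call few lists. Dlk1, an imprinted Notch-like ligand, went from 127.2 ± 8.39 TPM (SD, n = 2) in WT to 0.0185 ± 0.00136 in AIF3. The inhibitory G protein subunit gene Gnai1 went from 29.3 ± 2.04 to 0.0689 ± 0.0146 TPM. The ephrin receptor gene Epha3 and Plxdc2 fell by 4.67 and 4.42 on the log2 scale. In the other direction, the carbonic anhydrase gene Car14 rose by 4.52 ± 0.06 (SE) and Slc16a3, which encodes a lactate transporter, rose from 1.03 ± 0.0671 to 30.0 ± 0.61 TPM. Gprc5c, an orphan receptor gene, and Gatm, whose product makes the creatine precursor, rose by 3.83 and 3.30. Adjusted p-values of these genes lay between 3.99e-07 for Dlk1 and 1.47e-06 for Gatm.

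Of 13003 genes tested with limma, 4138 were higher and 3966 lower in AIF3 than in WT at an adjusted p under 0.05. At least 2-fold changes made up 288 of the higher and 652 of the lower genes. With RLE size factors more genes were lower than higher, 4153 against 3946. The median log2 fold change over all tested genes was 0.02.

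Of 23 tested Hox genes, 12 fell and 5 rose, and adjusted over the list alone 12 fell and 5 rose. Hox genes, which mark position along the body axis, had a median log2 fold change of -0.28 and no camera call (adjusted p = 0.0739). Hoxc10 was at 0.0328 ± 0.0464 TPM in WT and 43.7 ± 2.48 in AIF3, and Hoxc11 was listed at 0 in both WT libraries and at 14.9 ± 0.00349 in AIF3. Hoxb9 went the other way, from 50.2 ± 2.62 to 1.49 ± 0.203 TPM, and Hoxa5 from 46.6 ± 1.39 to 16.9 ± 0.623. The AIF3-AIF libraries had 47.2 and 42.8 TPM of Hoxc10 and 1.44 and 2.23 of Hoxb9, with adjusted p = 0.719 and 0.356 against AIF3. Hoxc11 was at 10.3 ± 0.632 TPM in AIF3-AIF and fell by 0.50 from AIF3, with adjusted p = 0.00375. Over the Hox list 4 genes rose and 3 fell between these lines, with no camera call (adjusted p = 0.525).

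**Figure D1:**
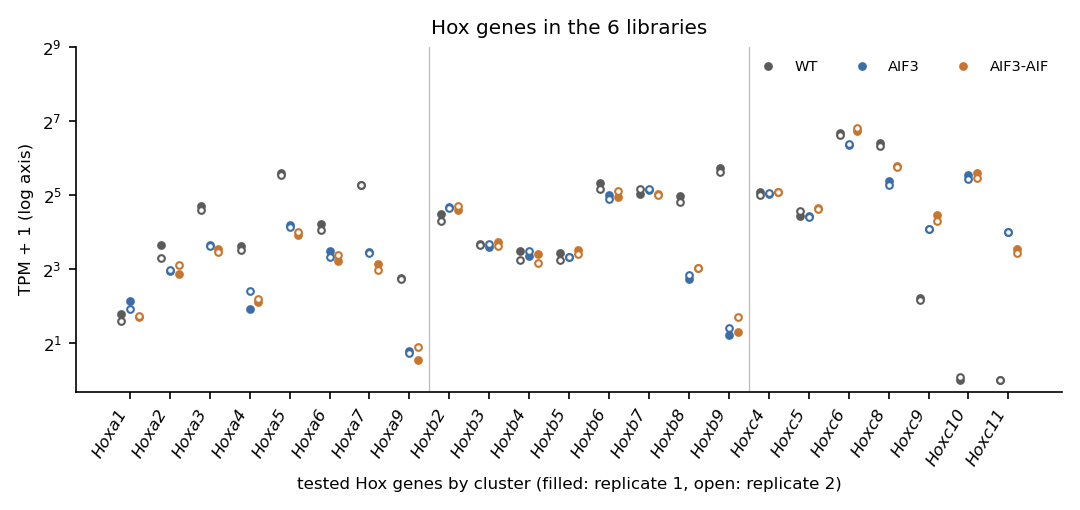
TPM + 1 of each tested Hox gene on a log axis in the 6 libraries, grouped by cluster; filled points are replicate 1 and open points replicate 2 of WT, AIF3 and AIF3-AIF. Hoxc10 and Hoxc11 were near or at 0 in WT only, while Hoxb9 was 50.2 ± 2.62 TPM in WT and under 3 in the 4 other libraries.

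Of 40 tested genes for collagens and extracellular matrix, 36 fell and 2 rose, and adjusted over the list alone 36 fell and 2 rose. Matrix genes had a median log2 fold change of -0.74 and a camera adjusted p = 1.36e-12, against an adjusted p = 0.376 with an estimated correlation. Col3a1, a fibrillar collagen, went from 439.4 ± 7.93 to 133.0 ± 0.822 TPM, and the matrix glycoprotein gene Tnc from 394.3 ± 8.56 to 148.1 ± 1.9. Of 20 tested myofibroblast contractile genes, 15 fell and 5 rose, and adjusted over the list alone 15 fell and 5 rose. Contractile genes had a median log2 fold change of -0.65 and a camera adjusted p = 3.54e-04, against an adjusted p = 0.376 with an estimated correlation. Smooth muscle actin Actg2 fell by 2.82 and calponin Cnn1 by 2.45. Of 18 tested imprinted growth genes, 16 fell and 2 rose, and adjusted over the list alone 16 fell and 2 rose. Imprinted genes had a median log2 fold change of -1.46 and a camera adjusted p = 1.32e-05, against an adjusted p = 0.376 with an estimated correlation. The growth-restraining RNA H19 went from 58.4 ± 0.926 to 3.98 ± 0.114 TPM, while Peg10 rose by 1.08. Of 14 tested fibroblast markers, 9 fell and 3 rose, and adjusted over the list alone 9 fell and 3 rose. These markers had a median log2 fold change of -0.47 and a camera adjusted p = 0.0445, against an adjusted p = 0.413 with an estimated correlation. The call ended without WT replicate 1 or 2, at adjusted p of 0.115 and 0.0509, and with RLE size factors, a filter of 1 TPM or the length trend removed, at 0.0504, 0.0735 and 0.0667. Over 18 camera alternatives it ran from 0.01 to 0.413. Thy1, a surface glycoprotein of fibroblasts, went from 232.7 ± 10.0 to 24.7 ± 0.171 TPM.

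Of 20 tested glycolysis genes, 17 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell. Glycolysis genes had a median log2 fold change of 0.46 and a camera adjusted p = 1.32e-05, against an adjusted p = 0.376 with an estimated correlation. Tpi1 and Pgk1, which encode enzymes of the pathway, rose by 0.85 and 0.71, and Pdk1, whose product restrains pyruvate oxidation in mitochondria, by 0.91. Of 20 tested hypoxia response genes, 13 rose and 4 fell, and adjusted over the list alone 13 rose and 5 fell. Hypoxia genes had a median log2 fold change of 0.40 and a camera adjusted p = 0.0247, against an adjusted p = 0.376 with an estimated correlation. The oxygen sensor gene Egln3 went from 11.7 ± 0.14 to 36.2 ± 0.0649 TPM and Bnip3, a mitophagy receptor gene, from 28.7 ± 0.713 to 74.8 ± 1.01. Of 30 tested DNA replication genes, 21 rose and 3 fell, and adjusted over the list alone 21 rose and 4 fell. Replication genes had a median log2 fold change of 0.32 and a camera adjusted p = 3.54e-04, against an adjusted p = 0.376 with an estimated correlation. Mcm10 and Mcm4, which encode replication factors, rose by 0.90 and 0.78, and Rrm1 fell by 0.45.

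Camera called 3 lists of genes for mitochondrial proteins higher in AIF3 than in WT, and 0 with an estimated correlation, where the lowest adjusted p was 0.376. Of 36 tested complex I subunits, 18 rose and 3 fell, and adjusted over the list alone 17 rose and 1 fell. Complex I genes had a median log2 fold change of 0.16 and a camera adjusted p = 0.0247, against an adjusted p = 0.557 with an estimated correlation. This call ended without WT replicate 1 and, separately, with the length trend removed, at adjusted p of 0.156 and 0.0855 in a range of 0.00156 to 0.557 over 18 camera alternatives. Ndufa1 rose by 0.58. Of 40 tested mitochondrial ribosome genes, 23 rose and 6 fell, and adjusted over the list alone 24 rose and 6 fell. Mitochondrial ribosome genes had a median log2 fold change of 0.20 and a camera adjusted p = 0.0073, against an adjusted p = 0.471 with an estimated correlation. Of 16 tested mitochondrial chaperones and proteases, 10 rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell. Chaperone and protease genes had a median log2 fold change of 0.22 and a camera adjusted p = 0.0247, against an adjusted p = 0.376 with an estimated correlation. Trap1, a chaperone gene, rose by 0.90. Of 39 tested complex II to V subunits, 14 rose and 7 fell, and adjusted over the list alone 14 rose and 7 fell. Complex II to V genes had a median log2 fold change of 0.05 and no camera call (adjusted p = 0.339). Of 30 tested genes for respiratory complex assembly and intermembrane import, 14 rose and 5 fell, and adjusted over the list alone 14 rose and 5 fell. Assembly genes had a median log2 fold change of 0.15 and no camera call (adjusted p = 0.0732). Of 17 tested tricarboxylic acid cycle genes, 8 rose and 3 fell, and adjusted over the list alone 8 rose and 3 fell. Cycle genes in AIF3 had a median log2 fold change of 0.05 and no camera call (adjusted p = 0.141). Of 17 tested fatty acid oxidation genes, 10 rose and 4 fell, and adjusted over the list alone 10 rose and 4 fell. Fatty acid oxidation genes had a median log2 fold change of 0.25 and no camera call (adjusted p = 0.0732). Chchd4, whose product works with AIF in protein import, went from 39.7 ± 2.92 to 59.5 ± 2.72 TPM.

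Of 28 tested integrated stress response genes, 18 fell and 3 rose, and adjusted over the list alone 18 fell and 3 rose. Stress response genes had a median log2 fold change of -0.25 and a camera adjusted p = 0.00261, against an adjusted p = 0.376 with an estimated correlation. The amino acid transporter genes Slc7a1 and Slc7a5 fell by 0.96 and 0.60, while Ddit4, an inhibitor of growth signalling, rose by 0.88. Of 24 tested cholesterol synthesis genes, 14 fell and 6 rose, and adjusted over the list alone 14 fell and 6 rose. Cholesterol genes had a median log2 fold change of -0.29 and a camera adjusted p = 0.0289, against an adjusted p = 0.376 with an estimated correlation. Of 12 tested AIF partners in cell death and relatives, 6 rose and 3 fell, and adjusted over the list alone 6 rose and 3 fell. The list's median was 0.11 and its mean -0.16, with no camera call (adjusted p = 0.498). Hspa1b went from 15.8 ± 1.01 to 3.35 ± 0.0234 TPM; it is nearly identical to Hspa1a, so reads may be split between the copies. Of 25 tested apoptosis regulators, 9 rose and 8 fell, and adjusted over the list alone 9 rose and 8 fell. Of 23 tested p53 targets, 9 fell and 7 rose, and adjusted over the list alone 11 fell and 7 rose. Neither list had a camera call, with adjusted p = 0.933 and 0.367. Casp6, an executioner caspase gene, rose by 1.03 and Pmaip1, a p53 target, fell by 1.92.

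**Figure D2:**
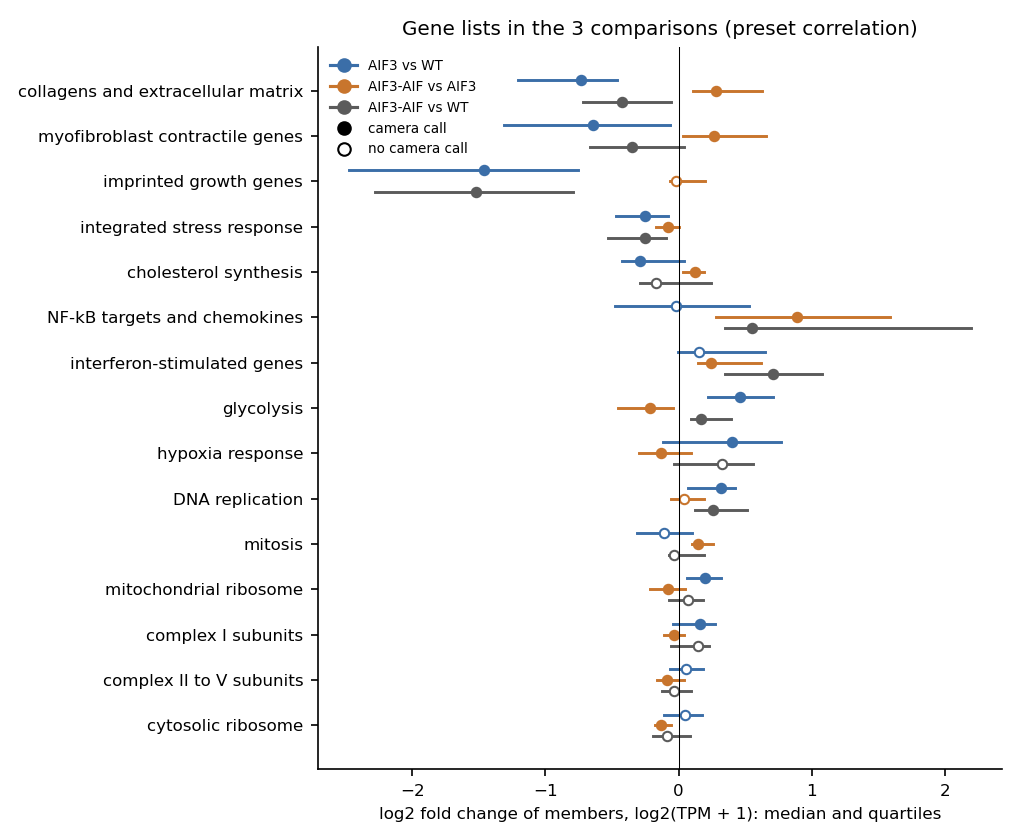
Log2 fold change, on log2(TPM + 1), of the members of 15 gene lists in the 3 comparisons; points are medians, lines run from the first to the third quartile, and filled points mark a camera call with the preset correlation. Matrix genes had medians of -0.74 in AIF3 vs WT, 0.28 in AIF3-AIF vs AIF3 and -0.42 in AIF3-AIF vs WT.

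The comparison of AIF3-AIF with AIF3 asks what returning AIF to the clone changes. No group held clone C3 put through the same steps without AIF. Effects of the added AIF therefore cannot be separated from those of its delivery, of selecting the line or of further culture. With the preset correlation, camera placed the lists of NF-kB targets, matrix, contractile and mitosis genes higher than other genes, and those of glycolysis, ribosome and respiratory complex genes lower. With an estimated correlation none of these calls was left, at adjusted p of 0.307 to 0.613. Wisp2, a matrix-associated signalling gene, went from 0.836 ± 0.309 to 23.1 ± 2.01 TPM and the cadherin gene Cdh11 from 8.25 ± 0.727 to 91.6 ± 2.7. The chemokine genes Cxcl1 and Ccl2 went from 13.4 ± 1.78 to 133.6 ± 0.13 TPM and from 88.8 ± 3.33 to 467.6 ± 8.22. Cbr2 and Ms4a4d rose by 2.43 and 2.36 on the log2 scale. Arhgdib went from 165.9 ± 0.829 to 37.9 ± 3.48 TPM, and Pparg, a nuclear receptor of adipocytes, from 38.7 ± 0.529 to 13.5 ± 1.43. The phosphodiesterase gene Pde3b fell by 2.05. Snord43, Snora33 and Mir22 fell by 1.98, 1.45 and 1.43, but these short genes lie within or beside longer transcripts and may share their reads. Without AIF3 replicate 2, Mir22 lost its call, at an adjusted p of 0.0662.

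limma called 3442 genes higher and 1739 lower in AIF3-AIF than in AIF3, of which 176 and 58 changed at least 2-fold. The higher share of 66.4% depended on scaling: RLE size factors gave 2622 higher and 2388 lower genes, a share of 52.3%. Without AIF3 replicate 1 the counts were 2002 and 924, without AIF3 replicate 2 they were 2158 and 867, and without AIF3-AIF replicate 2 the lower count was 1136.

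Of 20 tested genes for NF-kB targets and chemokines, 17 rose and 0 fell, and adjusted over the list alone 17 rose and 1 fell. NF-kB targets had a median log2 fold change of 0.89 and a camera adjusted p = 2.33e-07, against an adjusted p = 0.307 with an estimated correlation. Nfkbia, the NF-kB inhibitor gene, went from 27.4 ± 1.78 to 82.7 ± 0.38 TPM, and the chemokine gene Ccl7 from 78.7 ± 1.8 to 294.2 ± 8.82. Of 22 tested interferon-stimulated genes, 11 rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell. Interferon-stimulated genes had a median log2 fold change of 0.24 and a camera adjusted p = 0.0249, against an adjusted p = 0.307 with an estimated correlation. Without AIF3-AIF replicate 1 the call ended, at an adjusted p of 0.113 in a range of 0.00655 to 0.307 over 18 camera alternatives. Gbp2 and the RNA sensor gene Ddx58 rose by 1.21 and 0.84. Of 40 tested genes for collagens and extracellular matrix, 29 rose and 2 fell, and adjusted over the list alone 29 rose and 2 fell. Collagen and matrix genes had a median log2 fold change of 0.28 and a camera adjusted p = 1.81e-06, against an adjusted p = 0.458 with an estimated correlation. Postn, a secreted matrix protein gene, went from 564.6 ± 10.1 to 1498 ± 15.4 TPM, while Mgp, an inhibitor of calcification, fell by 1.37. Of 20 tested myofibroblast contractile genes, 13 rose and 2 fell, and adjusted over the list alone 13 rose and 2 fell. The contractile list had a median log2 fold change of 0.27 and a camera adjusted p = 0.00314, against an adjusted p = 0.307 with an estimated correlation. Tpm1 rose by 0.58. Of 30 tested mitosis genes, 21 rose and 1 fell, and adjusted over the list alone 22 rose and 2 fell. Mitosis genes had a median log2 fold change of 0.15 and a camera adjusted p = 5.68e-04, against an adjusted p = 0.307 with an estimated correlation. Nusap1 and Kif23, which act on the spindle, rose by 0.50 and 0.41. Of 24 tested cholesterol synthesis genes, 12 rose and 0 fell, and adjusted over the list alone 13 rose and 0 fell. The cholesterol list had a median log2 fold change of 0.12 and a camera adjusted p = 0.0326, against an adjusted p = 0.307 with an estimated correlation. RLE size factors, leaving out AIF3-AIF replicate 1, and removal of the length trend or of chromosome medians ended this call, at adjusted p of 0.0843, 0.051, 0.0907 and 0.294 in a camera range of 0.00741 to 0.307.

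Of 20 tested glycolysis genes, 13 fell and 2 rose, and adjusted over the list alone 13 fell and 2 rose. The glycolysis list had a median log2 fold change of -0.21 and a camera adjusted p = 9.60e-07, against an adjusted p = 0.307 with an estimated correlation. Tpi1, Gapdh and Hk2 fell by 0.47, 0.51 and 0.59. All lie on chromosome 6, whose genes shifted as a whole between these lines. The glycolysis list kept its preset-correlation call with chromosome medians removed. Of 20 tested hypoxia response genes, 8 fell and 4 rose, and adjusted over the list alone 11 fell and 5 rose. The hypoxia list had a median log2 fold change of -0.13 and a camera adjusted p = 0.0174, against an adjusted p = 0.307 with an estimated correlation. Of 40 tested cytosolic ribosome genes, 19 fell and 1 rose, and adjusted over the list alone 20 fell and 1 rose. Ribosomal protein genes had a median log2 fold change of -0.13 and a camera adjusted p = 4.44e-07, against an adjusted p = 0.523 with an estimated correlation. Quantile normalization ended this call and fry, which tests a list without the other genes, did not make it, at adjusted p of 0.397 and 0.0954 in a camera range of 2.51e-10 to 0.523. Many of these genes have processed pseudogenes, with which reads may be shared. Rpl32 and Rpl12 fell by 0.43 and 0.30. Of 23 tested NRF2 antioxidant genes, 13 fell and 4 rose, and adjusted over the list alone 13 fell and 4 rose. Antioxidant genes had a median log2 fold change of -0.13 and a camera adjusted p = 0.00408, against an adjusted p = 0.307 with an estimated correlation. Srxn1 and Nqo1, which encode redox enzymes, fell by 0.49 and 0.44. Of 28 tested integrated stress response genes, 9 fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose. The stress response list had a median log2 fold change of -0.08 and a camera adjusted p = 0.00237, against an adjusted p = 0.307 with an estimated correlation. Mthfd2, a mitochondrial folate enzyme gene, fell by 0.48.

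Of 40 tested mitochondrial ribosome genes, 13 fell and 1 rose, and adjusted over the list alone 13 fell and 1 rose. The mitochondrial ribosome list had a median log2 fold change of -0.08 and a camera adjusted p = 7.88e-04, against an adjusted p = 0.458 with an estimated correlation. Of 16 tested mitochondrial chaperones and proteases, 8 fell and 2 rose, and adjusted over the list alone 8 fell and 2 rose. The chaperone list had a median log2 fold change of -0.11 and a camera adjusted p = 0.00245, against an adjusted p = 0.307 with an estimated correlation. Of 39 tested complex II to V subunits, 12 fell and 2 rose, and adjusted over the list alone 12 fell and 2 rose. Genes of complexes II to V had a median log2 fold change of -0.09 and a camera adjusted p = 0.00255, against an adjusted p = 0.523 with an estimated correlation. Of 36 tested complex I subunits, 6 fell and 1 rose, and adjusted over the list alone 4 fell and 1 rose. Complex I subunits had a median log2 fold change of -0.04 and a camera adjusted p = 0.0301, against an adjusted p = 0.613 with an estimated correlation. Of 30 tested genes for respiratory complex assembly and intermembrane import, 8 fell and 1 rose, and adjusted over the list alone 8 fell and 1 rose. The assembly list had a median log2 fold change of -0.06 and a camera adjusted p = 0.0153, against an adjusted p = 0.523 with an estimated correlation. Of 17 tested tricarboxylic acid cycle genes, 5 fell and 2 rose, and adjusted over the list alone 5 fell and 2 rose. Cycle genes had a median log2 fold change of -0.03 and a camera adjusted p = 0.0445, against an adjusted p = 0.317 with an estimated correlation. Without AIF3-AIF replicate 2, complex I had an adjusted p of 0.24, and complexes II to V, assembly and the cycle lists 0.0721 each. With the length trend removed, the values for complex I and assembly were 0.376 and 0.0736. Without a filter on low values, the cycle list had 0.0597. fry did not call complex I, complexes II to V or assembly, with adjusted p of 0.482, 0.166 and 0.104. Over 18 camera alternatives these ran from 0.00349 to 0.613 for complex I, 1.03e-05 to 0.523 for complexes II to V, 0.00157 to 0.523 for assembly and 0.00751 to 0.317 for the cycle. Of 17 tested fatty acid oxidation genes, 8 rose and 2 fell, and adjusted over the list alone 8 rose and 3 fell. Fatty acid oxidation, in this comparison, had a median log2 fold change of 0.09 and no camera call (adjusted p = 0.525). Mrps6 fell by 1.21, Chchd4 by 0.65 and Cycs, which encodes cytochrome c, by 0.27; Chchd4 and Cycs lie on chromosome 6, and the Cycs call ended once chromosome medians were removed.

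Expression that differed between AIF3 and WT moved back in AIF3-AIF for 2979 genes, that is, genes called in AIF3 vs WT and called the opposite way in AIF3-AIF vs AIF3. They made up 1092 of the 4138 genes higher in AIF3 and 1887 of the 3966 lower ones. Among the genes lower in AIF3, Cdh11 was 119.0 ± 7.48 TPM in WT, 8.25 ± 0.727 in AIF3 and 91.6 ± 2.7 in AIF3-AIF. The activin antagonist gene Fst followed with 81.6 and 78.4 TPM in the WT libraries and means of 6.21 ± 0.216 in AIF3 and 30.6 ± 2.82 in AIF3-AIF, and Socs2, a feedback inhibitor of cytokine signalling, with 18.2 ± 0.388, 1.77 ± 0.246 and 12.2 ± 0.025. Plxdc2, Fbn2, Piezo2 and Aspn also moved back, by 2.64, 2.48, 2.15 and 1.84 on the log2 scale, and stayed lower than in WT. Wisp2 went beyond WT, at 5.36 ± 0.126 TPM there. Among the genes higher in AIF3, Arhgdib was 41.9 ± 1.06 TPM in WT, 165.9 ± 0.829 in AIF3 and 37.9 ± 3.48 in AIF3-AIF. Thbd, Adcyap1r1, Ramp3, Slco2a1, Peg10 and Tmcc3 fell by 1.30, 1.25, 1.21, 1.14, 0.93 and 1.08. Snora34 fell by 0.99, with adjusted p = 0.0427, a call that ended without AIF3 replicate 2 and without either AIF3-AIF library.

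Both comparisons use the AIF3 libraries. Simulated unchanged groups sharing those libraries gave 0.14 moved-back genes on average and at most 1. Almost no gene can be called in unchanged groups, so this count was near 0 in advance and does not measure what the sharing adds. Independent lists of these sizes would share 553 and 1050 genes. Genes that moved further from WT numbered 636 and 204, against 1095 and 530 from independent lists. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had r = -0.40, beside -0.51 in the simulations, and a covariance of -0.0807, beside -0.00776. Part of the excess may come from the shared libraries. With AIF3 replicate 1 set against WT and replicate 2 against AIF3-AIF, a test added after the data were seen, 517 higher and 1151 lower genes moved back, where independent lists would share 230 and 520. With the replicates exchanged the numbers were 513 and 1179, against 223 and 547. Each such fit rests on a single AIF3 library, whose spread is taken from the other groups. Without AIF3 replicate 1 or 2, 1729 and 1771 genes moved back. Of genes changed at least 2-fold, 98 of 288 higher and 328 of 652 lower ones moved back, but 88.9% and 91.3% were still called the same way in AIF3-AIF vs WT. The median share of the change that moved back was 8.60% for the higher and 22.7% for the lower ones. Over all called genes, 76.8% of the higher and 64.9% of the lower ones were still called the same way. Their median shares moved back were 10.2% and 38.5%. These shares are from TPM as deposited, where the median change of all tested genes in AIF3-AIF vs AIF3 was 0.051. With RLE size factors that median was 0.0044. Such an offset raises the share of the lower genes and reduces that of the higher ones. The difference between the directions may therefore come from scaling, and shares under other scalings were not measured.

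**Figure D3:**
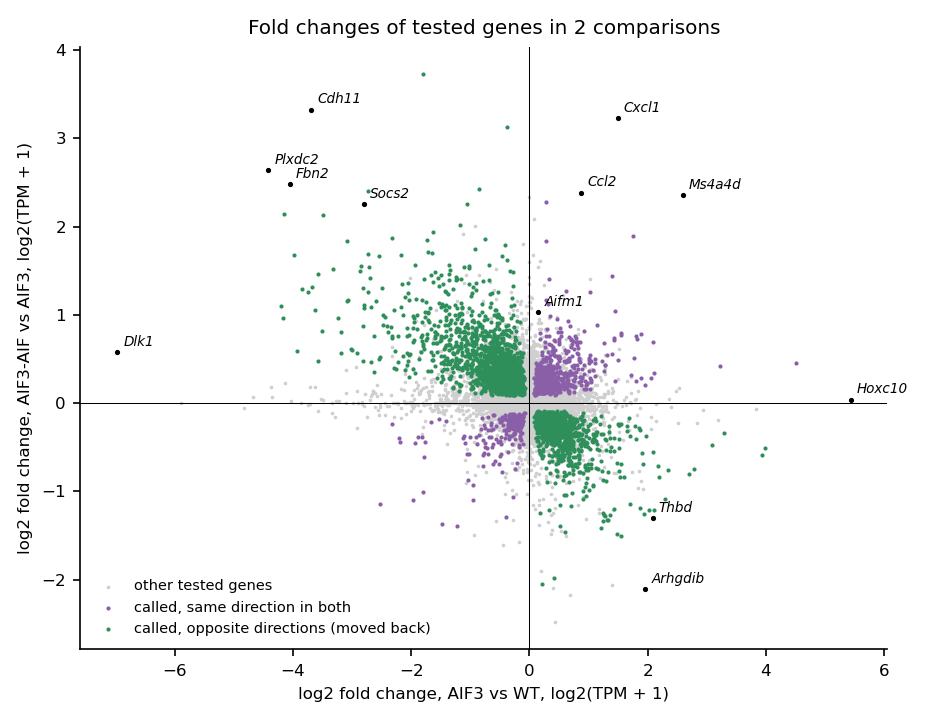
Log2 fold change of each tested gene, on log2(TPM + 1), in AIF3 vs WT (horizontal) and AIF3-AIF vs AIF3 (vertical). Green points are the 2979 genes called in opposite directions and purple points the 636 higher and 204 lower genes called in the same direction; the AIF3 libraries enter both axes.

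The comparison of AIF3-AIF with WT asks which differences remained or appeared in the rescued line. Large changes were shared with the AIF3 clone: Dlk1 was at 0.531 ± 0.192 TPM, Gnai1 at 0.0301 ± 0.00419 and Epha3 at 0.0966 ± 0.0135. Pde8a, a phosphodiesterase gene, fell by 4.29 on the log2 scale, and Hoxb9 fell by 4.19. Hoxc10, Car14 and Gprc5c rose by 5.48, 4.97 and 3.77, and the potassium channel gene Kcnd2 by 3.65. Cxcl1 and Ms4a4d, at 4.13 ± 0.597 and 0.104 ± 0.0262 TPM in WT, rose by 4.72 and 4.95.

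limma called 4562 genes higher and 3213 lower in AIF3-AIF than in WT, with 367 and 463 changed at least 2-fold. The higher share of 58.7% became 48.1% with RLE size factors, which gave 3734 higher and 4028 lower genes. Among the genes called in AIF3-AIF vs AIF3, 1362 had not been called in AIF3 vs WT, and 1077 of those were called in AIF3-AIF vs WT. Some genes were called in AIF3-AIF vs WT alone, a class set by the thresholds, since the differences between the calls were not tested. Among them Camkmt and Cyp4f17 rose by 0.65 and 0.56, and Snord98 and Mir684-1 by 2.43 and 0.71. Snord98 was at 6.43 and 0 TPM in the WT libraries, so the size of its rise leans on the library at 0. Mir7079, Mir7654, Mir3572 and Snora61 fell by 0.90, 0.82, 0.67 and 0.60. Only Camkmt kept its call whichever library was left out; the 7 others lost it in at least 1 such run, at an adjusted p of 0.051 to 0.189.

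Of 22 tested interferon-stimulated genes, 16 rose and 0 fell, and adjusted over the list alone 17 rose and 0 fell. The interferon list had a median log2 fold change of 0.71 and a camera adjusted p = 3.73e-04, against an adjusted p = 0.249 with an estimated correlation. Trim30a went from 0.277 ± 0.014 TPM in WT to 3.47 ± 0.0271 in AIF3 and 3.62 ± 0.0748 in AIF3-AIF, and the RNA sensor gene Ifih1 from 1.1 ± 0.178 to 2.74 ± 0.202 and 4.48 ± 0.0347. Of 20 tested genes for NF-kB targets and chemokines, 16 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell. The NF-kB list had a median log2 fold change of 0.55 and a camera adjusted p = 1.38e-04, against an adjusted p = 0.249 with an estimated correlation. Ccl7 and Ccl2 rose by 3.64 and 3.25. Of 18 tested imprinted growth genes, 15 fell and 2 rose, and adjusted over the list alone 15 fell and 2 rose. The imprinted list had a median log2 fold change of -1.52 and a camera adjusted p = 1.38e-07, against an adjusted p = 0.288 with an estimated correlation. Slc38a4, an imprinted amino acid transporter gene, went from 137.3 ± 6.7 to 47.4 ± 2.42 TPM. Of 40 tested genes for collagens and extracellular matrix, 29 fell and 6 rose, and adjusted over the list alone 29 fell and 6 rose. The matrix list had a median log2 fold change of -0.42 and a camera adjusted p = 1.38e-07, against an adjusted p = 0.442 with an estimated correlation. Of 28 tested integrated stress response genes, 20 fell and 2 rose, and adjusted over the list alone 20 fell and 2 rose. Integrated stress response genes had a median log2 fold change of -0.25 and a camera adjusted p = 4.83e-06, against an adjusted p = 0.249 with an estimated correlation. Slc7a1 fell by 1.07 and Mthfd2 by 0.66.

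Of 30 tested DNA replication genes, 22 rose and 3 fell, and adjusted over the list alone 23 rose and 3 fell. The replication list had a median log2 fold change of 0.26 and a camera adjusted p = 1.45e-04, against an adjusted p = 0.249 with an estimated correlation. Of 20 tested myofibroblast contractile genes, 13 fell and 4 rose, and adjusted over the list alone 14 fell and 4 rose. Myofibroblast genes had a median log2 fold change of -0.35 and a camera adjusted p = 7.71e-04, against an adjusted p = 0.249 with an estimated correlation. Of 20 tested glycolysis genes, 14 rose and 2 fell, and adjusted over the list alone 15 rose and 2 fell. Glycolytic genes had a median log2 fold change of 0.17 and a camera adjusted p = 0.011, against an adjusted p = 0.531 with an estimated correlation. Pfkfb3, which makes an activator of glycolysis, rose by 1.07. Of 17 tested fatty acid oxidation genes, 12 rose and 0 fell, and adjusted over the list alone 12 rose and 0 fell. Oxidation genes had a median log2 fold change of 0.25 and a camera adjusted p = 0.0124, against an adjusted p = 0.531 with an estimated correlation. Acadvl rose by 0.67. Of 24 tested autophagy and mitophagy genes, 14 rose and 2 fell, and adjusted over the list alone 15 rose and 2 fell. Autophagy genes had a median log2 fold change of 0.18 and a camera adjusted p = 0.0147, against an adjusted p = 0.394 with an estimated correlation. Sqstm1, a cargo receptor gene, rose by 0.51, while Map1lc3a fell by 0.52. Complex I genes in this comparison had a median log2 fold change of 0.15 and no camera call (adjusted p = 0.185). Mitochondrial ribosome genes here had a median log2 fold change of 0.07 and no camera call (adjusted p = 0.59).

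Markers of other cell types were measured as a check on the cultures. Xist, the RNA made from an inactive X chromosome, was at 177 and 155 TPM in WT, 28.7 and 27.3 in AIF3, and 12.1 and 12.2 in AIF3-AIF. The Y-linked genes listed, Uba1y and Erdr1, were close to 0 and not tested. The macrophage gene Cd14 was at 9.41 ± 0.969 TPM in WT, 24.4 ± 0.623 in AIF3 and 23.0 ± 2.17 in AIF3-AIF. Csf1r, another macrophage gene, was at 0.193 ± 0.0889, 0.751 ± 0.201 and 0.202 ± 0.0934 TPM, and Lyz2 was at 1.06 ± 0.663, 1.46 ± 0.308 and 3.33 ± 0.0461 TPM in WT, AIF3 and AIF3-AIF. The endothelial receptor gene Flt1 was at 42.4 ± 1.26, 12.5 ± 0.0377 and 27.4 ± 1.38 TPM, the neural gene Nes at 93.8 ± 0.346, 39.8 ± 0.177 and 52.6 ± 0.185, and Tubb3 at 49.8 ± 1.41, 9.03 ± 0.717 and 17.2 ± 1.34. Neural markers were also tested as a list. In AIF3 vs WT, 4 fell and 2 rose, with a median log2 fold change of -0.85 and no camera call (adjusted p = 0.0739). In AIF3-AIF vs WT, 4 fell and 1 rose, with a median of -0.60 and no camera call (adjusted p = 0.096). The values that follow are for AIF3-AIF vs AIF3. Of 6 tested neural and Schwann cell markers, 4 rose and 0 fell, and adjusted over the list alone 4 rose and 0 fell. Neural markers had a median log2 fold change of 0.41 and a camera adjusted p = 0.0471, against an adjusted p = 0.307 with an estimated correlation. Without a filter on low values the median was 0.0015 and the call ended, at an adjusted p of 0.466. It ended also without AIF3-AIF replicate 1 (0.051), with a replicate block (0.0578), a pseudocount of 0.1 TPM (0.0533) and chromosome medians removed (0.0957), in a range of 0.0207 to 0.466 over 18 camera alternatives. The epithelial gene Krt19, the muscle gene Des and the erythroid gene Epor stayed under 3 TPM in every library.

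Genes of some chromosomes were shifted together. Over 9969 genes with a mean of at least 5 TPM, the median log2 fold change in AIF3 vs WT was 0.35 on chromosome 16, 0.29 on 11, 0.27 on 18, 0.21 on 6 and 0.20 on X. It was -0.31 on chromosome 9 and -0.20 on chromosome 7. In AIF3-AIF vs AIF3 the medians were 0.21 on chromosome 9 and -0.16 on chromosome 6, beside 0.16 on 13, 0.15 on 4 and X, and 0.14 on 1. Of the genes higher in AIF3, 62.6% on chromosome 6 (201 of 321) and 29.5% on chromosome 11 (190 of 644) moved back, against 26.4% over all chromosomes. Among the other chromosomes shifted up, the share was 38.2% on 16, 8.44% on 18 and 8.02% on X. Of the lower genes, 65.9% on chromosome 1, 65.1% on 9 (300 of 461) and 64.6% on 4 moved back, against 47.6% over all chromosomes. On chromosome 7, shifted down like 9, 30.1% did. Chromosome 1 was not shifted down in AIF3, with a median of 0.08 in AIF3 vs WT and 0.21 in AIF3-AIF vs WT. Of its higher genes, 17.5% moved back, so its share of lower genes goes with a rise of the chromosome rather than a return. With the median of each chromosome removed in every library, an alternative added after the data were seen, 2388 genes moved back. The X chromosome's median exceeded that of the autosomes by 0.18 in AIF3 vs WT, 0.11 in AIF3-AIF vs AIF3 and 0.28 in AIF3-AIF vs WT. Each had a two-sided permutation p = 1e-04 over 10000 assignments of genes, the smallest they can give. This does not set X apart from shifted autosomes: in AIF3 vs WT, chromosomes 16, 11, 18 and 6 had larger medians than X.

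**Figure D4:**
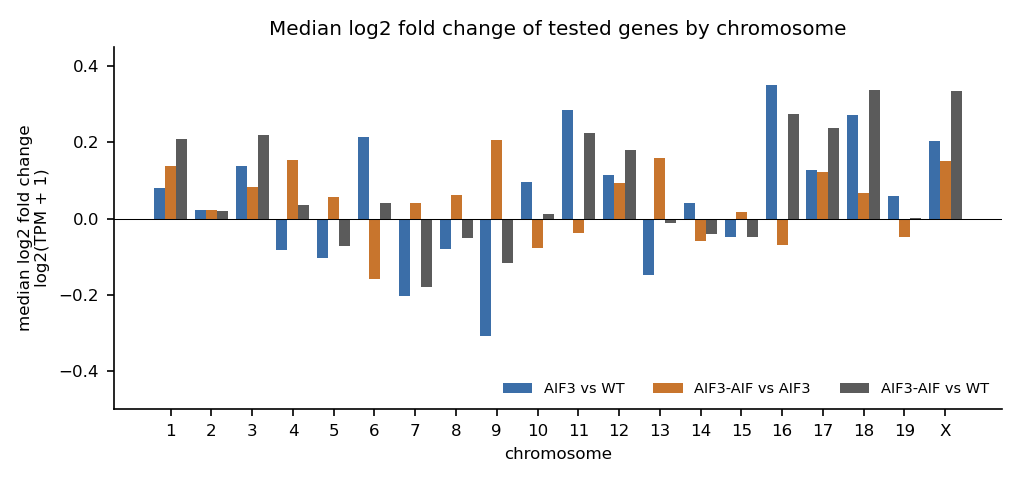
Median log2 fold change of tested genes with a mean of at least 5 TPM on each chromosome, on log2(TPM + 1), in the 3 comparisons. Chromosome 9 had medians of -0.31 in AIF3 vs WT and 0.21 in AIF3-AIF vs AIF3, and chromosome 6 of 0.21 and -0.16.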

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

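Tests with another pseudocount, voom, quantile normalization, trends or chromosome medians removed, small RNA genes left out, and the AIF3 libraries split were chosen after the data were seen. Of 206 alternative values for 10 counts, 183 lay within 1.5 times the main count. A minimum absolute log2 fold change of 1 left 288 higher and 652 lower genes in AIF3 vs WT, 176 and 58 in AIF3-AIF vs AIF3, 367 and 463 in AIF3-AIF vs WT, and 117 moved back, by construction. voom on recovered reads called 3193 higher and 2844 lower genes in AIF3-AIF vs AIF3, 4963 and 3659 in AIF3 vs WT, and 4733 and 3427 in AIF3-AIF vs WT; the cause was not tested. The higher share in AIF3-AIF vs AIF3 was 53.8% with upper-quartile factors, 50.2% with quantile normalization, 52.9% with voom, 52.4% with the length trend removed and 53.1% with the GC trend removed. Leaving out 1 library gave 2002 to 3537 higher and 867 to 1876 lower genes in AIF3-AIF vs AIF3, and 1729 to 2918 moved back. The lone library left in a group is then assumed to vary like the other groups. RLE size factors gave 2968 moved-back genes, voom 3586 and removal of chromosome medians 2388. With 1 AIF3 library against WT and the other against AIF3-AIF, 1668 and 1692 genes moved back in the 2 ways of splitting them.

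With an estimated correlation 0 lists were called in AIF3 vs WT, 0 in AIF3-AIF vs AIF3 and 0 in AIF3-AIF vs WT, against 12, 18 and 10 with the preset correlation. The estimated version rests on 3 residual degrees of freedom, so these losses do not show that correlation between genes made the calls. fry, which does not compare a list with other genes, called 27 lists in AIF3 vs WT, 23 in AIF3-AIF vs AIF3 and 21 in AIF3-AIF vs WT. In AIF3-AIF vs AIF3 it did not call complex I (adjusted p = 0.482), complexes II to V (0.166), assembly (0.104) or the cytosolic ribosome (0.0954). With chromosome medians removed, 21 lists were called in AIF3 vs WT; the cause was not tested. Of 760 alternative values for the 40 called lists, 691 kept the call and the direction, 69 lost the call and 0 changed direction. Every leave-one-out kept the call for 31 lists.

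Of 9245 alternative values for 465 named-gene changes, 9094 kept the call and the direction and 149 lost the call. With chromosome medians removed, Aifm1 in AIF3 vs WT became -0.0238 (adjusted p = 0.623) and Sdhd 0.00570 (adjusted p = 0.886), where subtracting the medians of X and 9 is by construction close to the whole change. DESeq2 was not run, and the split of higher and lower calls depended on scaling as given with each comparison.

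A replicate block changed the counts to 4028 higher and 3895 lower genes in AIF3 vs WT, 3177 and 1615 in AIF3-AIF vs AIF3, and 4417 and 3101 in AIF3-AIF vs WT, with 2784 moved back. Same-numbered libraries did not deviate together, with r across genes of -0.015, 0.045 and 0.019 between groups, so the numbers were not taken as paired. With 2 simulated libraries per group and each gene's estimated spread, a change of 0.25 on the log2 scale was called in 44% of genes. Few simulated genes were changed, while 62.3% were called in AIF3 vs WT, which loosens the adjusted threshold. The 44% is therefore not the sensitivity reached in the data.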

Other observations

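Markers and enzymes not yet described differed between the lines, with the lists taken in AIF3 vs WT. Of 5 tested adipocyte markers, 3 rose and 2 fell, and adjusted over the list alone 3 rose and 2 fell. Adipocyte markers had a median log2 fold change of 0.45 and no camera call (adjusted p = 0.498). Lpl, which encodes lipoprotein lipase, was at 69.6 ± 1.93 TPM in WT, 95.6 ± 0.883 in AIF3 and 117.5 ± 3.77 in AIF3-AIF, and Cebpa at 1.53 ± 0.147, 0.0497 ± 0.0201 and 0.0928 ± 0.0384. Of 18 tested endoplasmic reticulum chaperones, 10 fell and 4 rose, and adjusted over the list alone 10 fell and 4 rose. Chaperones of the endoplasmic reticulum had a median log2 fold change of -0.15 and no camera call (adjusted p = 0.0732). Xbp1, a transcription factor gene of the unfolded protein response, was at 64.0 ± 0.689, 37.5 ± 0.897 and 54.3 ± 1.43 TPM, and Hspa5 at 880.2 ± 41.6, 605.6 ± 20.2 and 691.5 ± 0.555. Gsta4, a detoxifying glutathione transferase gene, was at 23.3 ± 0.261, 110.5 ± 1.4 and 61.5 ± 6.2 TPM. Spp1, a bone marker gene, was at 256.9 ± 2.42, 230.5 ± 4.73 and 183.7 ± 1.18 TPM.

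The tests of random placement of genes, of chromosome parts, of length on complex I and assembly genes, and of length, GC content or chromosome medians removed were chosen only after the result was seen.

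With the preset correlation, camera called 7 lists of genes for mitochondrial and ribosomal proteins lower in AIF3-AIF than in AIF3; for the 5 tested here, of respiratory complexes, assembly and ribosomes, an estimated correlation left 0 calls, at adjusted p of 0.458 to 0.613, and fry called the mitochondrial ribosome list alone. Transcript length bias as the whole cause is argued against by 3 of the 5 lists still called lower with the length trend removed, GC content bias by 5 of 5, and copy number of whole chromosomes by 5 of 5 with chromosome medians removed. For complex I and assembly genes, transcript length bias cannot be told apart: both calls, 2 of 2, ended with the trend removed, at adjusted p = 0.376 and 0.0736. The complex I median went from -0.04 (quartiles -0.11 and 0.04) to -0.02 (-0.11 and 0.06), and that of assembly from -0.06 (-0.20 and 0.07) to -0.07 (-0.22 and 0.05), so for assembly the call ended without a smaller median. The length trend between AIF3-AIF and AIF3 had rho = 0.17 across genes, beside 0.19 between the AIF3-AIF replicates, and an effect of the returned AIF or of selecting the line stays open and untested.

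Whole chromosomes were shifted between AIF3 and WT, with an SD of the 20 chromosome medians of 0.173, beside 0.00369 to 0.0125 between replicates. Chance placement of genes is argued against by a permutation p = 1e-04, the smallest that 10000 assignments can give, and transcript length or GC content bias by 96.7% of the SD left with both trends removed. Copy number of whole chromosomes is a candidate explanation. For this, each of the 20 chromosomes was parted at its middle gene. Of 11 parts with an absolute median of at least 0.2, 10 (90.9%) had a partner part of the same sign and at least 0.1. The exception lay on chromosome 3. These 11 parts came from 8 chromosomes, so where both parts passed 0.2, each counted as the other's partner. Chromosome 16 met the limits with unequal parts, at medians of 0.45 and 0.19. Gains and losses of chromosomes could differ between cell lines for reasons of culture. Part of the AIF3 vs WT difference and of the moved-back genes may follow them. No DNA measurement was used here.

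Among genes at least 10 TPM in one of AIF3 and WT and under 0.5 TPM in the other, 10% (3 of 30) moved back by at least 50% in AIF3-AIF. Of the other genes changed at least 2-fold and at least 10 TPM in one of the lines, 27.9% (104 of 373) did, with a two-sided Fisher's exact p = 0.0321, but this test is void, since genes with a larger difference need a larger return on the log2 scale and neighbouring genes are not independent. A difference of origin between the lines, such as the embryo or body region sampled, cannot be told apart from a lasting effect of AIF3. Both would leave such genes unreturned, and each genotype is a single line. The 10% lay at the bound set for a difference of origin, but a lower share would not have separated these explanations either. Hoxc10, Hoxc11 and Dlk1 belonged to the 30, while Plxdc2, Fbn2 and Piezo2 were the 3 that moved back.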
